A study of Homo sapiens with 40 samples.

How the data were processed

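The study compared human HEK293 Flp-in T-REx cells, an embryonic kidney line with an inducible integration site, that express an α-amanitin-resistant RNA polymerase II large subunit (Rpb1) of the wild type (WT) or with 1 substitution, R749H, H1106Y or E1126G. Per the labels' protocols, the transgene was induced with doxycycline for 12 to 16 h and the endogenous polymerase was then blocked with α-amanitin for 42 h. The labels list 40 samples. RNA-seq had 6 libraries, 2 each of WT, R749H and E1126G, each deposited as 2 mate files of 100 bp reads. RASL-seq, which counts ligated probe pairs at chosen exon junctions, had 12 libraries, 3 of each of the 4 genotypes. The 16 GRO-seq libraries, 4 per genotype, are not analysed here. The labels do not say whether libraries of a genotype came from separate cultures.

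The 7 deposited tables are the authors' own comparisons of a mutant with WT, and they hold no value per library. The tables whose names carry a code in place of a mutant were taken as R749H because the labels of the R749H samples list them. Each row gives a skipped exon, or a retained intron, with its coordinates and 3 values. The first deposited value is the natural log of the WT ratio of inclusion to exclusion reads, and the second is the log2 change of that ratio in the mutant. The third is the p-value the authors deposited, which is not adjusted. The test behind it, and whether the spread between libraries entered it, are not given in the sources used here. The submitters' processing notes name TopHat 1.4.1, Bowtie 0.12.7 and edgeR 3.7.17 without saying which table each made. Coordinates are those of the deposited tables, in the human GRCh37 build per the submitters' processing notes, and are printed 1-based.

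Log bases and signs were checked on the values. With the natural log, the WT ratio was a ratio of whole numbers (denominator up to 300, relative tolerance 1e-09) for 62.6% to 94.4% of events, against at most 0.396% with base 2. With log2 of mutant over WT, the mutant ratio was whole for 63.7% to 95.2% of events, against 4.51% to 22.5% with the opposite sign. The WT value was identical in every table of an assay for every shared event, 13284 of 13284 between the RNA-seq exon tables. In the intron tables a higher value was read as more retention, because 40 of the 45 gaps under 40 nt, too short to be spliced, lay above the midpoint, with a median of 96.6% against 35.1% for the other 2654.

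Inclusion was computed as 100 times the ratio divided by 1 plus the ratio, for WT and mutant. It is not corrected for an included exon having more junctions to count than a skipped one, and probe efficiency differs between RASL-seq junctions, so levels are compared within an assay. The p-values were adjusted by the Benjamini-Hochberg method over all events of a table, with a threshold of 0.05. Because the sequencing depth is unknown and no library has its own value, no standard deviation, interval of a level or leave-one-out value is given. The deposited p-values compare these libraries, and whether they carry the spread between them is unknown. The binomial, Fisher's and permutation p-values are across events or genes of these libraries.

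The counts of higher and lower events were compared by exact two-sided binomial tests, and overlaps by two-sided Fisher's exact tests. Correlations across events and differences in median log10 length had two-sided permutation tests with 100000 permutations, whose smallest p is 1e-05. Events are not independent replicates, since exons of a gene share reads. Because mutants of an assay share the WT libraries, unchanged mutants were simulated in 100 draws from the errors implied by the deposited p-values, with WT noise and mutant noise given equal parts of the smaller of the variances. The difference between mutants in an event was tested by an approximate z from the same errors, a test chosen after seeing the data because no reads per library could be used. That z treats the comparisons as independent, which is conservative under a shared WT only if the implied errors hold. Tested on simulated data for the 2129 RASL-seq events of R749H, the calls recovered 81.5% of 200 events changed by a log2 of 2 and 99.5% at 4. For the 13284 RNA-seq exon events of R749H these shares were 24% and 84.5%, and for the 2521 introns 64.5% and 92.5%. False calls were 5.23% to 7.69% of the calls. The simulated noise had the same implied errors as its test, so this share lies near the threshold by construction. It does not measure false calls in the data, and the recovered shares also rest on those errors. The approximate test between mutants recovered less, 4% and 53% for RNA-seq exons, 31.5% and 83.5% for introns and 69.5% and 98.5% for RASL-seq. If the implied errors hold, its counts miss many differences.

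Gene symbols were looked up from the Ensembl identifiers in the tables, and 6156 of the 6332 identifiers in the R749H RNA-seq exon table had one. Introns carry no gene in the tables. Of 2699 introns, 631 took the gene of an exon event with the same intron ends, 105 that of a skipped span around them, 16 lay in more than 1 gene and 1947 are given by coordinates. The 9 gene lists were fixed before the data were examined, and 317 of their 401 genes had a tested exon event after 8 older symbols were matched through the RefSeq gene names of assembly GRCh38.p14. Lists were tested by Fisher's exact test over genes with adjustment over the lists of a comparison. The genes named were chosen by a rule set before the data were examined. It takes per comparison the 10 changed events with the largest increase and the 10 with the largest decrease in inclusion, 1 per gene with the smallest adjusted p. It adds up to 4 members per list changed in at least 2 comparisons, 5 events changed the same way in most comparisons and 5 that went opposite ways in R749H and E1126G. The rule's read minimum of 20 and its check in every library apply only where reads are given, so they were not used. Some genes that the rule takes are not reported here. The planned count tests with edgeR and DESeq2 were not run, because the files hold no counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The alternatives were thresholds of 0.01 and 0.1, a minimum change of 10 percentage points, 1 event per gene, genes for events, matching by symbol and mean for median length. Counting identical rows once, a WT inclusion of 5% to 95%, directions around the median, pairs of mutants from different assays, the shared events with an unadjusted p under 0.05, skipped spans, the spans of opposite events against events higher in both mutants and the exon length limit of 27 nt were added after seeing the data. Length and correlation alternatives used 10000 permutations.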

Results

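Splicing was compared between cells running on WT RNA polymerase II and cells running on R749H, H1106Y or E1126G polymerase. Residues of this kind alter how fast the polymerase moves, with R749H and H1106Y known as slow and E1126G as fast forms. The question was how exon skipping and intron retention respond to the elongation rate. RNA-seq covered WT, R749H and E1126G with 2 libraries each, and RASL-seq covered WT and the 3 mutants with 3 libraries each. All levels below are pooled values from the authors' deposited tables, with no error per library and unknown depth, and adjusted p-values were computed from the deposited p-values.

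In R749H cells the poison exon of the splicing factor SRSF3, whose inclusion brings in a premature stop codon, was switched from mostly skipped to mostly included. In the authors' deposited table this 456-nt exon (chromosome 6, 36567598 to 36568053) rose from 10.4% to 83.7% inclusion in RNA-seq, a log2 change of 5.47 with an adjusted p of 5.8e-67. An exon of MCM3, a subunit of the replicative helicase, rose from 10.5% to 78.2% in the authors' deposited table, and one of HNRNPDL, an hnRNP, from 23.6% to 88.6%. Exons of ARHGAP26, ZBTB21, MPHOSPH8, TM2D1 and CR2 were also among the 10 largest increases, which spanned 63.9 to 75.3 percentage points. SMPD4BP and FAM86FP were in that group too, but these are pseudogenes whose reads can come from near-identical copies, so their values are uncertain. Among decreases, exons of TRAK2, an adaptor of kinesin motors, went from 86.4% to 9.5% and of RNF146, a ubiquitin ligase, from 87.3% to 12.0% in the authors' deposited table. Exons of SLC9A5, POU6F1, ST7 and ZFX and of the unnamed gene ENSG00000232995 fell as well. A 63-nt exon of BBS5, part of the ciliary BBSome, fell from 91.5% to 14.3% in the authors' deposited table, and the same exon is listed again under ENSG00000251569. PMS2CL, a pseudogene of PMS2, is uncertain for the same reason as SMPD4BP.

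Over the transcriptome, 2169 of 14358 exon events in 1606 genes changed in R749H, 1015 with higher and 1154 with lower inclusion. The share higher, 46.8% (exact 95% interval 44.7 to 48.9), differed from an even split by an exact binomial test (adjusted p = 0.0043). With events of 5% to 95% WT inclusion alone, the share was 50.1% and no longer differed (adjusted p = 0.94). A change of at least 10 percentage points was reached by 655 of the higher and 779 of the lower events.

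Of the fixed gene lists, 4 held more changed genes than the rest in R749H RNA-seq. Among SR proteins and their relatives, which promote exon definition, 14 of 22 genes changed, 11 of them with higher events alone, against 25.2% of other genes (Fisher's exact test, adjusted p = 7.4e-04). Of their 55 events, 22 changed over all events tested and 30 adjusted over the list alone. In TRA2A an exon rose from 34.5% to 56.1% and in ACIN1 one rose from 20.4% to 61.7% in the authors' deposited table. Cytoskeleton and adhesion genes changed in 28 of 48 cases (adjusted p = 1.7e-05), 19 with lower events alone. Of their 198 events, 39 changed, and 40 adjusted over the list alone. An 18-nt exon of MACF1, which links actin and microtubules, fell from 76.7% to 25.0%, and an 84-nt exon of EPB41L1 from 55.6% to 2.5%, in the authors' deposited table. These genes had 4.12 tested events each against 2.25 in other genes, and counted over events the list did not pass (adjusted p = 0.22). Chromatin genes changed in 18 of 38 cases (adjusted p = 0.012), a call that was also lost over events (adjusted p = 0.24). The hnRNP and splicing regulator list changed in 19 of 42 cases (adjusted p = 0.015). The 110 chromatin events held 23 changed ones and 26 adjusted over the list alone, and the 127 regulator events 34 and 37.

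The other 5 lists did not pass in R749H RNA-seq. Apoptosis genes changed in 10 of 23 cases (adjusted p = 0.082), as did 3′ end and RNA surveillance genes in 10 of 23 (adjusted p = 0.082). The latter passed with events called at 0.01 (odds ratio 3.15, adjusted p = 0.017) and at 0.1 (2.85, adjusted p = 0.023). The p53 and cell cycle list had 11 of 33, core spliceosome genes 12 of 40 and polymerase II elongation genes 9 of 33. Adjusted over the list alone, these 5 lists held 14, 15, 19, 16 and 13 changed events in that order, against 13, 13, 18, 14 and 11 over all events.

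**Figure D1:**
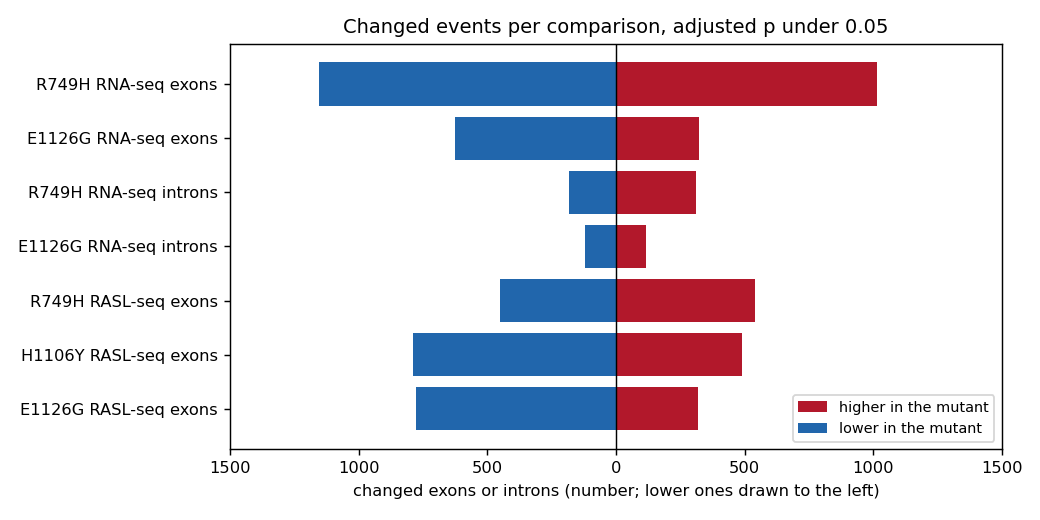
Number of changed exons or introns per comparison on the horizontal axis, with events higher in the mutant in red to the right and lower in blue to the left. E1126G shows 323 higher against 626 lower exons in RNA-seq and 321 against 777 in RASL-seq.

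In E1126G cells the largest decrease was in GK, glycerol kinase. Its 18-nt exon fell from 87.0% to 5.0% inclusion in the authors' deposited table, a log2 change of -7.00 with an adjusted p of 5e-12. A 63-nt exon of EPB41, the membrane skeleton protein 4.1R, fell from 89.7% to 13.8%, and a 57-nt exon of CLSTN1 from 91.1% to 27.4%, in the authors' deposited table. Exons of TCF7L2, LRP8, PLA2G6, INF2, SLIT2, BRSK2 and PICALM completed the 10 largest decreases, which ran from 55.6 to 82.0 points as absolute sizes. Increases were seen in MEGF6, EFR3A, EBF3, OBSL1, ITSN1, AUH, ZNF300 and CR2. A 54-nt exon of MBNL2, a splicing regulator, rose from 30.8% to 83.0% and the HNRNPDL exon from 23.6% to 69.9% in the authors' deposited table.

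E1126G changed 949 of 14650 exon events in 759 genes, 323 higher and 626 lower. The share higher was 34.0% (exact 95% interval 31.0 to 37.1; binomial adjusted p = 1.6e-22). The median log2 change of all events was -0.08, and around it the counts of higher and lower events did not move. The calls were still those made against no change, so this does not test a shift of all events.

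SR genes changed in 11 of 22 cases in E1126G RNA-seq, 8 with higher events alone, against 11.7% of other genes (Fisher's exact test, adjusted p = 5.6e-05). Of their 60 events 15 changed, and 19 adjusted over the list alone. A 79-nt exon of TRA2A rose from 31.8% to 77.4% in the authors' deposited table. Cytoskeleton and adhesion genes changed in 22 of 48 cases, 20 with lower events alone (adjusted p = 3.8e-08). Of their 208 events 32 changed, and 34 adjusted over the list alone. These genes had 4.33 tested events each against 2.275 in other genes, which raises the chance that a gene holds a changed event. Counted over events, this list still passed. The other 7 lists did not pass. Chromatin genes changed in 9 of 37 cases (adjusted p = 0.10) and splicing regulators in 9 of 42 (odds ratio 2.04, adjusted p = 0.20). Regulators passed with events called at 0.01 (odds ratio 3.50, adjusted p = 0.013) and at 0.1 (2.67, adjusted p = 0.014), and chromatin genes at 0.1 (2.56, adjusted p = 0.025). Core spliceosome genes changed in 6 of 42 cases, 3′ end and surveillance genes in 4 of 24, elongation genes in 3 of 34, p53 and cell cycle genes in 3 of 33 and apoptosis genes in 3 of 23 (adjusted p = 0.79 for each). Adjusted over the list alone, these 7 lists held 17, 17, 6, 7, 2, 4 and 7 changed events in that order, against 12, 11, 6, 6, 3, 4 and 6 over all events.

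Introns were retained more often than lost in R749H cells. An intron on chromosome 11, 117094025 to 117094793, rose from 3.4% to 76.8% retention in the authors' deposited table, a log2 change of 6.57 with an adjusted p of 2e-19. A 3545-nt intron of SCARB1, a lipoprotein receptor, rose from 22.8% to 78.6%, and an intron of ADD1, adducin, from 20.0% to 75.0%, in the authors' deposited table. An intron of NDUFAF7, a complex I assembly factor, fell from 62.1% to 14.7% and one of IL12A from 52.6% to 15% in the authors' deposited table. FAM86B1, also among the decreases, belongs to a family of near-identical copies. In E1126G an intron of TSPAN31 rose from 12.9% to 94.4% in the authors' deposited table, while an intron of TRA2A fell from 86.5% to 43.2%. TSPAN31 has the gene CDK4 beside it on the opposite strand, and whether reads were assigned by strand is not given in the sources used here, so its value is uncertain. Introns of OGG1, a DNA glycosylase, of KCNC4, a potassium channel, and of NDUFAF7 also fell, and one of TPCN1 rose.

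R749H changed 492 of 2605 introns, 310 with more and 182 with less retention, a share of 63.0% higher (exact 95% interval 58.6 to 67.3; binomial adjusted p = 1.5e-08). E1126G changed 240 of 2615, 118 with more and 122 with less (49.2%, adjusted p = 0.85). At a threshold of 0.01 the E1126G share turned to 54.3% (adjusted p = 0.40).

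On RASL-seq, R749H raised exons of SRRM2 and PALLD, a splicing cofactor and an actin-associated protein. The 273-nt SRRM2 exon rose from 31.1% to 82.6% in the authors' deposited table and the 672-nt PALLD exon from 17.8% to 69.2%. In RNA-seq the same SRRM2 exon was mostly included already, and rose from 91.4% to 99.2% in R749H in the authors' deposited table. Exons of USPL1, DENND2B, MAPK3, NR2C2AP, CHD5, PLAG1, BAZ2A and LEF1 were the other large increases. A 77-nt exon of PDK1 fell from 61.0% to 13.8% and a 24-nt exon of TNIK from 90.9% to 47.7% in the authors' deposited table. SLIT2, FBXL13, ZBED3-AS1, ARAP1, XIAP, EXOC7, ASCC2 and SLAIN1 completed the decreases. Of 2248 events 991 changed, 540 higher and 451 lower (54.5%, exact binomial adjusted p = 0.0060). At a threshold of 0.01 the share was 53.1% (adjusted p = 0.11), and with WT inclusion of 5% to 95% it was 53.03% (adjusted p = 0.18).

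In H1106Y cells exons of CCNT1, the cyclin of the elongation factor P-TEFb, and of DIS3, an exosome nuclease, rose strongly. The 164-nt CCNT1 exon went from 17.5% to 86.0% and the 68-nt DIS3 exon from 7.2% to 63.2% in the authors' deposited table. H1106Y had no RNA-seq, where the same CCNT1 exon stood at 83.0% in WT and 98.6% in R749H in the authors' deposited table. Exons of RCC1, TRA2A, SRSF3, RFC5, ARHGEF28, USPL1 and ACIN1 rose too, by 54.5 to 68.5 points over the group. A 167-nt exon of ITSN1 fell from 91.6% to 18.3% and one of RAB6A, a Golgi GTPase, from 96.9% to 35.5% in the authors' deposited table. EFCAB14, MARK3, SLIT2, PROM1, CDKL3, CCSER2, OSBPL6 and APBB2 also lost exons. H1106Y changed 1282 of 2070 events, 491 higher and 791 lower (38.3%, exact binomial adjusted p = 1.1e-16), and the median log2 change of all events was -0.33. With the same calls and only the direction taken around that median, 38.5% were higher, which does not remove a shift of all events. Higher events had a median WT inclusion of 42.1% and lower ones 79.9%. In a check not planned beforehand, change correlated with the WT log ratio across events (Pearson's r = -0.30). On RASL-seq this r was 0.01 in R749H and -0.06 in E1126G. Without RNA-seq of H1106Y, a property of its libraries cannot be told apart from an effect of the mutation.

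On RASL-seq, E1126G lowered exons of the membrane skeleton genes EPB41 and SPTAN1. The EPB41 exon fell from 82.0% to 23.1% and a 60-nt exon of SPTAN1, α-spectrin, from 70.6% to 23.1% in the authors' deposited table. MARK3, SLIT2, PTPN4, MAP3K8, ADGRG6, PROM1, NKTR and APBA1 had the other large decreases. Exons of SUOX, RFC5, PALLD, PLAG1, ALCAM, C11orf54, CLCN6, SRSF3, DYSF and BEND6 rose. Of 2312 events 1098 changed, 321 higher and 777 lower (29.2%, exact binomial adjusted p = 2.5e-43), with a median log2 change of -0.37 over all events. With the same calls and only the direction taken around that median, the share was 30.9%. Calls were made against no change, so this does not remove a shift of all events.

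None of the 9 lists passed in RASL-seq, where 48.4% to 65.0% of the other genes changed. The SR list changed in 10 of 14 genes in R749H and in H1106Y, and in 12 of 17 in E1126G. Its events changed in 14, 17 and 17 cases in that order, both over all events and adjusted over the list alone. Cytoskeleton genes changed in 19 of 28, 24 of 29 and 22 of 33 cases, with 14, 14 and 17 genes having lower events alone. The smallest adjusted p was that of apoptosis genes in E1126G, with 3 of 15 changed (adjusted p = 0.16), against 12 of 13 in H1106Y (adjusted p = 0.22). With events called at 0.01, apoptosis genes in E1126G (odds ratio 0.0906, adjusted p = 0.026) and cytoskeleton genes in H1106Y (3.78, adjusted p = 0.035) passed, and counted over events cytoskeleton genes in R749H did (2.39, adjusted p = 0.019). Apoptosis genes changed in 9 of 15 cases in R749H. Chromatin genes changed in 17 of 26, 17 of 25 and 18 of 27 cases, splicing regulators in 14 of 22, 15 of 20 and 15 of 22, and p53 and cell cycle genes in 8 of 17, 13 of 16 and 8 of 17. Core spliceosome genes changed in 4, 8 and 7 of 12 cases, elongation genes in 5, 4 and 5 of 6, and 3′ end and surveillance genes in 7 of 10, 9 of 10 and 6 of 11. Adjusted over the list alone, cytoskeleton genes held 36, 41 and 38 changed events, apoptosis genes 14, 15 and 5, chromatin genes 18, 22 and 20, and splicing regulators 18, 23 and 18. For p53 genes these were 8, 17 and 15, for core spliceosome genes 4, 8 and 7, for elongation genes 5, 5 and 8 and for surveillance genes 12, 13 and 10. Over all events the numbers were 35, 40 and 38 for cytoskeleton, 13, 15 and 5 for apoptosis, 18, 20 and 20 for chromatin, 10, 18 and 15 for p53 and 11, 13 and 9 for surveillance genes, and the same for the others. Among members, the 45-nt exon of FIP1L1, a polyadenylation factor, fell from 30.5% to 6.9%, 4.3% and 14.7% in R749H, H1106Y and E1126G in the authors' deposited table. An exon of UPF3B, which acts in nonsense-mediated decay, fell from 68.1% to 41.6%, 14.5% and 22.7% in R749H, H1106Y and E1126G in the authors' deposited table. An exon of APAF1, part of the apoptosome, rose in H1106Y from 30.8% to 82.4% in the authors' deposited table.

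Exons that changed in both the slow R749H and the fast E1126G mostly went the same way, while most changed exons of RNA-seq were called in 1 mutant. The EPB41 exon and a 24-nt exon of the guidance ligand SLIT2 fell in all 5 exon comparisons, as did a 27-nt exon of the kinase MARK3. The SRSF3 exon and a 126-nt exon of RFC5, a clamp loader subunit, rose in all 5. A 1474-nt exon of SNRNP70, the U1 snRNP protein, fell from 40.1% to 10.4% in R749H and to 14.4% in E1126G on RNA-seq in the authors' deposited table. Of 1430 exon events present in all 5 tables, 74 changed in all 5, 20 higher throughout, 48 lower throughout and 6 mixed.

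Among 13284 exon events tested in both RNA-seq comparisons, 527 changed in both, against 149 for independent lists, and 518 of these (98.3%, exact 95% interval 96.8 to 99.2) went the same way. Both were higher in 196 and both lower in 322, against 23.5 and 52.4 for independent lists, and R749H higher with E1126G lower in 9 against 46.0. Of introns, 123 changed in both, against 46.4 for independent lists, and 122 went the same way, 72 with more and 50 with less retention against 14.2 and 8.81. On RASL-seq the same-direction share was 84.9% for R749H and E1126G (603 events), 89.0% for R749H and H1106Y (699) and 75.9% for H1106Y and E1126G (747). Independent lists would share 487, 589 and 657 events in that order. Both were higher in 194, 295 and 158 events against 77.2, 123 and 71.5, and both lower in 318, 327 and 409 against 157, 166 and 290.1. Simulated unchanged mutants on the same WT went the same way in 99.5% of RNA-seq exons and 99.5% of introns with an unadjusted p under 0.05 in both, and in 99.3%, 99.5% and 98.8% for those RASL-seq pairs. Over events chosen in the same way, the observed shares were 95.7%, 96.2%, 84.9%, 88.4% and 75.4% in that order. The simulation had 102 such exons and 20.2 such introns on average, and 15.1, 15.3 and 13.6 events for the RASL-seq pairs, against 1266, 292, 717, 787 and 844 observed. Log2 changes correlated across events with Pearson's r of 0.50 for RNA-seq exons, 0.55 for introns, and 0.58, 0.62 and 0.40 for those RASL-seq pairs (Spearman's rho 0.48, 0.54, 0.56, 0.62 and 0.37; permutation p = 1e-05 for each, the smallest possible, also after adjustment). Simulated unchanged mutants on the same WT gave r of 0.41, 0.41, 0.41, 0.41 and 0.38 in that order. For H1106Y and E1126G the observed 0.40 lay close to the simulated 0.38. Permutation takes the changes of a pair as unrelated, which is untrue with a shared WT. Its p-values therefore cannot show change beyond the shared WT, and the numbers for independent lists ignore it too. Covariances were 0.841, 0.664, 0.756, 1.31 and 0.800, against 0.332, 0.225, 0.0851, 0.0905 and 0.0761 in the simulation. The covariances lay 0.509, 0.440, 0.671, 1.22 and 0.724 above the simulated ones. The simulated values rest on the errors implied by the deposited p-values. If spread between libraries did not enter those, the simulated WT noise is too small and these gaps too large. The WT libraries could not be divided between the mutants without values per library, so part of the shared change may come from them. R749H in RNA-seq and E1126G in RASL-seq, which share no library, gave r = 0.50 and a covariance of 0.865 across events, and E1126G in RNA-seq and R749H in RASL-seq gave 0.35 and 0.516 (pairs chosen after seeing the data).

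**Figure D2:**
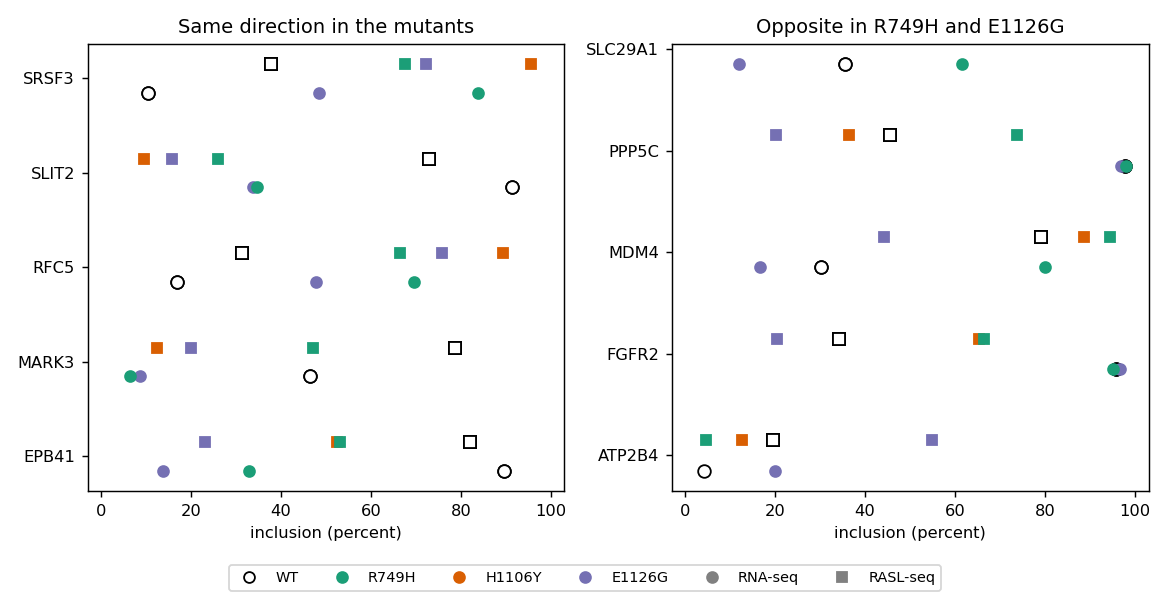
Inclusion in percent of 5 exons that changed the same way in the mutants (left) and 5 that changed opposite ways in R749H and E1126G (right), with open symbols for WT, colours for mutants, circles for RNA-seq and squares for RASL-seq. SRSF3 lies at 10.4% in WT RNA-seq and at 83.7% in R749H.

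By the approximate test, 230 of 13231 RNA-seq exon events and 77 of 2516 introns differed between R749H and E1126G, and 720 of 2128 RASL-seq events did. H1106Y differed from R749H in 825 of 1987 RASL-seq events and from E1126G in 977 of 1984. R749H lay above E1126G in 156, 52 and 577 of the differing events, in the order RNA-seq exons, introns and RASL-seq. On RASL-seq the median log2 change of all events was 0.05 in R749H and -0.37 in E1126G. The test does not remove that offset, which tilts the differing RASL-seq events toward R749H.

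The same mutant gave like directions in both assays. Of 1648 events measured in both for R749H, 897 changed in either and 768 (85.6%) went the same way, and for E1126G 748 of 899 (83.2%) did. Pearson's r across events was 0.64 for R749H and 0.59 for E1126G (Spearman's rho 0.64 and 0.59; permutation p = 1e-05, the smallest possible). Of events changed in both assays, 271 of 276 went the same way in R749H and 177 of 178 in E1126G. Different mutants across assays also mostly went the same way among events changed in either. R749H RNA-seq did so in 76.5% with E1126G and 74.9% with H1106Y RASL-seq. E1126G RNA-seq did so in 65.6% with R749H and 61.6% with H1106Y. Over all events of each assay, the share higher among changed R749H events was 46.8% on RNA-seq and 54.5% on RASL-seq. WT levels themselves correlated with r = 0.73 on the natural log scale. The FGFR2 exon on chromosome 10 stood at 95.9% in WT RNA-seq and 34.2% in WT RASL-seq in the authors' deposited tables.

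Exons that rose were longer, and exons that fell shorter, than exons without a call. In R749H RNA-seq the median was 124 nt for higher, 88.0 nt for lower and 109 nt for other exons, and in E1126G 136 and 77.5 nt against 109 nt (permutation test, adjusted p = 2.2e-05 for each). RASL-seq gave 111 and 87.0 nt against 99.0 nt in R749H (adjusted p = 0.0038 and 0.0016), and 134 and 81.0 nt against 105 nt in E1126G (adjusted p = 2.2e-05 for both). In H1106Y higher exons had 108 nt against 95 nt (adjusted p = 0.0035), while lower exons did not pass at 96.0 nt (adjusted p = 0.96). Of exons of at most 27 nt, such as those of MARK3, SLIT2 and MACF1, 45 of 56 changed ones fell in R749H RNA-seq, against 52.5% of longer changed exons (Fisher's exact test, adjusted p = 1.5e-04). In E1126G RNA-seq 38 of 44 did, against 65.0% (adjusted p = 0.0049), and in R749H RASL-seq 24 of 32, against 44.5% (adjusted p = 0.0022). The shares did not pass in H1106Y RASL-seq, with 23 of 33 against 61.5% (adjusted p = 0.37), or in E1126G RASL-seq, with 33 of 39 against 70.3% (adjusted p = 0.089). The length limit of 27 nt was chosen after seeing the data.

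Introns that gained retention were longer than introns without a call. Their median was 460 nt in R749H and 397.5 nt in E1126G, against 208 and 221 nt without a call (permutation test, adjusted p = 2.2e-05 for both). Introns that lost retention had medians of 151 and 167.5 nt (adjusted p = 0.0038 and 0.036). With mean log10 length the difference for lost introns no longer passed in either mutant (adjusted p = 0.082 and 0.31), nor did that of E1126G with events called at 0.01 (adjusted p = 0.14).

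**Figure D3:**
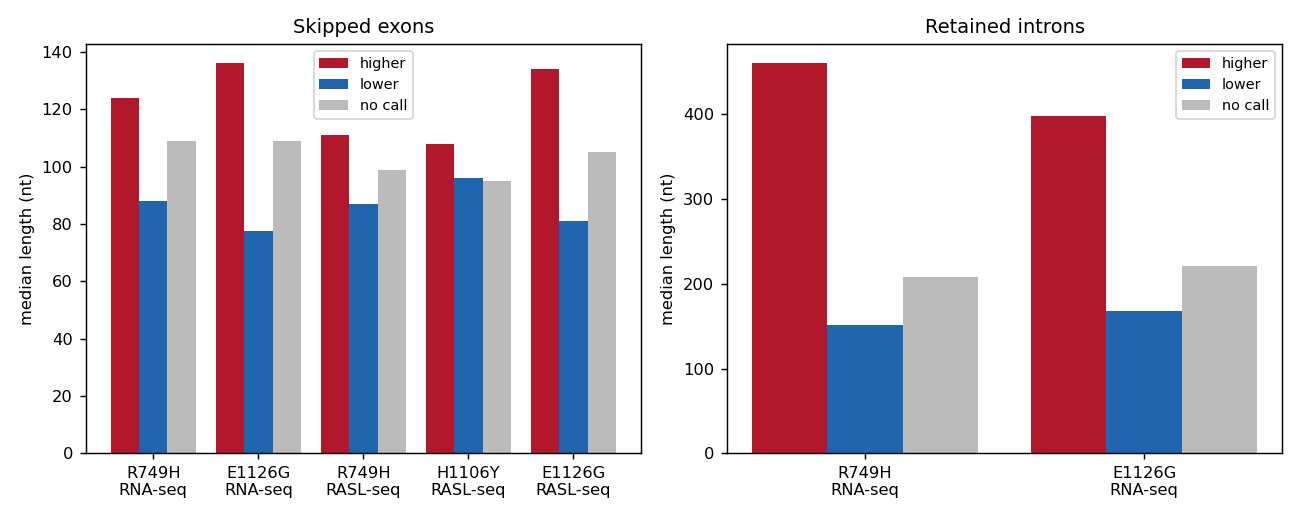
Median length in nt of skipped exons (left) and retained introns (right) for events higher, lower and without a call in each comparison. Higher introns reach 460 nt in R749H against 208 nt without a call.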

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

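All tests in this part except the RNA-seq check of the opposite events and the RNA-seq median over events of both assays were chosen after the results were seen, as were the share among other events beside that check and the comparisons of spans, and what would count against the span hypothesis was changed after its values were known.

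Exons of 5 genes were called in opposite directions in R749H and E1126G. They were chosen for that, and each of the 91 RASL-seq and 9 RNA-seq events so called passed the approximate test between mutants, so that test adds nothing to the calls of those assays. The 39-nt exon of MDM4, a p53 inhibitor, rose in R749H and fell in E1126G on RASL-seq, a log2 difference of 4.41, and in RNA-seq the difference of 4.32 did not pass (adjusted p = 0.21). PPP5C differed by 3.48 and FGFR2 by 2.94 on RASL-seq, but their RNA-seq differences of 0.74 and -0.57 did not pass (adjusted p = 0.85 and 0.98). In WT these exons stood at 97.7% and 95.9% in RNA-seq, against 45.5% and 34.2% on RASL-seq. The approximate test recovered 4% and 53% of simulated RNA-seq exon differences of log2 2 and 4. Not passing in RNA-seq is therefore no evidence of equal change. ATP2B4 went the other way, lower in R749H and higher in E1126G, with a difference of -4.63 on RASL-seq. SLC29A1 differed by 3.55 in RNA-seq.

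Events changed in both R749H and E1126G mostly went the same way, although their polymerases differ from WT in opposite speed. Chance values of the shared WT libraries are argued against by pairs that share no library, since 93.3% of 282 events changed in R749H RNA-seq and E1126G RASL-seq went the same way (exact 95% interval 89.7 to 95.9). Both were higher in 76 and both lower in 187, against 24.1 and 93.8 for independent lists, while 16 and 3 went opposite ways. Chance differences between cultures stay open, since the labels do not say whether the WT libraries of the assays came from separate cultures. For E1126G RNA-seq and R749H RASL-seq the share was 90.8% of 131. A WT line that itself differs from every mutant line cannot be told apart from an effect of altered speed, because there is 1 WT line and H1106Y also went the way of E1126G from the other assay in 71.2% of 153 events. The mutations themselves remain an untested biological explanation.

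Changed events of E1126G were mostly lower on RASL-seq. A shift of those libraries as the whole cause is argued against by RNA-seq, where 34.0% of 949 changed events were higher (exact 95% interval 31.0 to 37.1). An even split is not a strict benchmark there, since R749H RNA-seq with the same WT had 46.8% higher. The E1126G interval lies below that share too. The median of all events is open. Over 1674 events of both assays the RNA-seq median log2 change was -0.24 (bootstrap 95% interval -0.28 to -0.18) and the RASL-seq median -0.38, so a part specific to RASL-seq cannot be told apart.

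RASL-seq events higher in R749H and lower in E1126G lay in long spans, with a median of 19382 nt between the flanking exons against 6417 nt for the 512 events changed the same way. Noise of the RASL-seq libraries is argued against by RNA-seq, where R749H lay above E1126G in 59 of 71 of them (83.1%, exact 95% interval 72.3 to 91.0), against 745 of 1467 other events (50.8%, Fisher's exact test, p = 3.7e-08). The hypothesis that exons needing a slow polymerase lie in long spans was formed from this difference in median log10 span, 0.48, or 0.59 from the 194 events higher in both (permutation p = 1e-05 for each, the smallest possible), which is therefore no test of it. H1106Y, also slow but sharing the WT libraries, was higher in 64 of 83. By the last version of its rule the hypothesis stays open. An earlier version, which compared opposite RNA-seq events with all events changed the same way, would have counted against it. The rule was narrowed after those values were seen. The 9 opposite RNA-seq events had a median span of 1401 nt against 3915 nt for the 518 changed the same way (permutation p = 0.028). Against the 196 higher in both they did not pass, a log10 difference of -0.17 (permutation p = 0.48). Over RNA-seq events changed in either mutant, R749H minus E1126G fell with the span, which goes against the hypothesis (Spearman's rho -0.311, 2527 events). On RASL-seq that difference rose weakly with the span (0.0952, 1435 events). The 83 RASL-seq events also had a median WT inclusion of 85.7%, against 68.0% for events higher in both and 52.0% for events lower in both.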

How the results depend on the processing

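The WT inclusion range, the directions around the median, the counting of identical rows and the approximate test between mutants came after seeing the data. All other alternatives were chosen before the data were examined. No paired analysis was possible because the tables hold no value per library, so leaving out replicates, other splits of the libraries, DESeq2, edgeR against the deposited p, TMM and read filters were not run either. Of the summary values recomputed under an alternative, 263 kept their direction and side of the threshold or stayed within 1.5 times the count, and those that did not follow. At a threshold of 0.01, R749H RNA-seq changed 1368 exons and 322 introns, and E1126G 502 and 116. With at least 10 percentage points, 1434, 604, 376, 680 and 414 exon events remained called in R749H and E1126G RNA-seq and R749H, H1106Y and E1126G RASL-seq. With WT inclusion of 5% to 95%, R749H RASL-seq had 660 and H1106Y 837. The share higher became 50.12% in R749H RNA-seq exons under that range and 54.31% in E1126G introns at 0.01. In R749H RASL-seq it was 53.03% under that range and 53.12% at 0.01. Events differing between R749H and E1126G numbered 116 at 0.01 and 355 at 0.1 for RNA-seq exons, and 34 and 123 for introns. The log10 length difference of lost introns was -0.0639 with the mean in R749H, and -0.0446 with the mean and -0.129 at 0.01 in E1126G. For lower exons of H1106Y it turned to -0.00455 at 0.01 and -0.00899 with the mean, without passing. Counted over events, the odds ratios of chromatin (1.49) and cytoskeleton (1.39) genes in R749H RNA-seq no longer passed, while cytoskeleton genes in R749H RASL-seq did (2.39). Lists that passed under a changed threshold were 3′ end and surveillance genes in R749H RNA-seq (3.15 at 0.01, 2.85 at 0.1), splicing regulators (3.50 and 2.67) and chromatin genes (2.56 at 0.1) in E1126G RNA-seq. At 0.01 cytoskeleton genes in H1106Y RASL-seq (3.78) and apoptosis genes in E1126G RASL-seq (0.0906) passed. At 0.1 elongation genes in R749H RASL-seq have no odds ratio, since every tested gene was called. The cause was not tested. Of the named exons and introns, 117 of 140 stayed past a threshold of 0.01. Depth is unknown, so events with few reads limit the calls to an extent that cannot be given.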

Other observations

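The tests of spans in this part were chosen after the data were seen, while the exons named in its last paragraph follow the rule set before.

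Over the events changed in either mutant, the difference of R749H minus E1126G fell with the skipped span in RNA-seq (Spearman's rho -0.311 across 2527 events) and rose weakly with it in RASL-seq (0.0952 across 1435 events). The permutation p was 1e-05, the smallest possible, and 2.3e-04. Exons higher in R749H RNA-seq had a median span of 2398 nt against 5301 nt without a call, and in E1126G 2670 nt against 5064 nt (permutation test, adjusted p = 2.2e-05 for both). On RASL-seq the spans of higher exons did not pass the test in R749H, at 8474 nt against 8600 nt (adjusted p = 0.95), and were 6862 against 8620 nt in H1106Y (adjusted p = 0.025) and 5830 against 9340 nt in E1126G (adjusted p = 2.2e-05). Exons that fell went both ways. In R749H they lay in longer spans on RNA-seq, 5898 nt (adjusted p = 0.020), and in shorter ones on RASL-seq, 7044 nt (adjusted p = 0.0078). In E1126G they lay in shorter spans on RNA-seq, 4448 nt (adjusted p = 0.048), and on RASL-seq, 7485 nt (adjusted p = 0.0036), and in H1106Y the 7743 nt did not pass (adjusted p = 0.22).

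Exons of CCNT2, SETD2 and SMARCA4 changed, but they do not stand for their gene lists. The polymerase II elongation list, which holds CCNT2 and SETD2, passed in no comparison at the main threshold. In R749H RNA-seq 27.3% of its genes changed against 25.3% of other genes, and in E1126G RNA-seq 8.8% against 11.9%. The chromatin list, which holds SMARCA4, passed at that threshold in R749H RNA-seq alone, a call that was lost over events. An 87-nt exon of CCNT2, a cyclin of P-TEFb, fell from 12.8% to 2.6% in R749H, 0.5% in H1106Y and 5.5% in E1126G on RASL-seq in the authors' deposited table, and a 283-nt exon of SETD2, the H3K36 methyltransferase, rose from 14.4% to 42.6% in R749H and 39.4% in E1126G RNA-seq. A 99-nt exon of SMARCA4 rose from 13.2% to 43.1% in R749H RNA-seq in the authors' deposited table. On RASL-seq it rose from 1.08% to 3.22% in R749H and 7.50% in H1106Y and fell to 0.784% in E1126G in the authors' deposited table.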
